A study of Arabidopsis thaliana with 12 samples.

How the data were processed

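The series holds chromatin immunoprecipitation with sequencing (ChIP-seq) of Arabidopsis thaliana seedlings of the Landsberg erecta (Ler) ecotype, 10 days old. Each line carried the locus of 1 protein fused to a 2xYPet-3xHA tag, per the labels, where YPet is a yellow fluorescent protein recognised by an antibody against GFP. The tagged proteins were REV, PHB, PHV, ICU4 and ATHB8, the class III homeodomain leucine-zipper (HD-ZIPIII) transcription factors, and TPL (TOPLESS), a co-repressor. Of the 12 samples, 6 were immunoprecipitations and 6 were the matching inputs. Each immunoprecipitation was represented by 1 peak list, so 6 lists entered the analysis and each group had 1 sample. The series text speaks of duplicates for each genotype, and whether these were pooled before the peaks were called is not given in the sources used here. No list came from plants without a tag, and files of the input samples were not used here.

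Reads were processed with Bowtie2 and peaks with MACS2 on the TAIR10 genome, per the submitters' processing notes, which give no versions or settings. Per the file headers, each peak has a start, an end, a length, a summit, a pileup, a p-value, a q-value and a fold enrichment, in the layout MACS2 writes. The authors' pileup is a coverage signal at the summit, deposited on a scale whose relation to the number of reads is not stated. The authors' p-value and q-value columns were deposited as −log10 values. The authors' fold enrichment is a linear ratio of the immunoprecipitated signal to the local background estimated by the peak caller, and per the series text each immunoprecipitation was set against its own input. The fold enrichment and q-value belong to a single peak of a single list. They were used to describe, rank, filter and compare peaks within that list, and ranks were averaged over lists only to choose genes to name. Positions were 1-based, since in all 5815 REV rows, and in every row of the other lists, the length equalled end minus start plus 1. The depth of the libraries is unknown, because the lists hold no read counts. The list named for ICU4 calls its peaks CNA, a synonym that the gene table gives for the same gene, ATHB15 (AT1G52150).

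Peaks on the 5 nuclear chromosomes were analysed. Gene names, and which genes lie next to a peak, came from the NCBI RefSeq gene table of assembly TAIR10.1, which has 27444 nuclear protein-coding genes with a locus tag and carries neither strand nor sequence. The plan had been to assign each summit to the nearest transcription start site and to divide summits among promoter, UTR, coding sequence and intron. Because the table used here has no strand and no exons, each summit was given to the nearest protein-coding gene, at a distance of 0 when inside it, if that gene lay within 2000 bp. Summits were classed as inside a gene, outside but within 2000 bp, or farther away. A summit was called gene-poor when fewer than 10 protein-coding genes lay within 50 kb to each side. The planned search for 10 motifs at the summits needs a genome sequence and was not run. A longer promoter and the authors' own gene annotation, both planned as alternatives, had no counterpart in the tables used and were not run either.

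Peaks of a pair of lists were counted as overlapping when they shared at least 1 bp. Each overlap was set beside 1000 circular shifts of the second list along each chromosome, with a one-sided permutation p whose smallest possible value is 0.001. For the 5 HD-ZIPIII lists, overlapping peaks were merged into regions, counted by the number of lists they held and compared with 1000 shifts of all 5 lists. Shares of peaks, regions or genes carry Wilson 95% intervals, which cover counting error only. Overlap of target gene sets was tested with the two-sided Fisher exact test over all nuclear protein-coding genes, with Benjamini-Hochberg adjustment over the 15 pairs. The same test was applied to 21 gene lists with 245 memberships, written before the data were examined, with adjustment over all 126 combinations of a gene list and a peak list. Of the memberships, 244 were matched to a protein-coding gene of the gene table, the exception being ZPR4, which the table classes as non-coding. One of the gene lists holds light-harvesting and RuBisCO small-subunit genes as a control for strongly transcribed loci. Differences in median fold enrichment within a list were tested with a two-sided permutation test with 100000 resamples, adjusted over 10 comparisons. Peaks and genes are not replicates of an experiment, so all of these p-values describe the lists and not the variation between plants.

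The genes named in the text were chosen by a rule fixed before the data were examined. They are the 5 HD-ZIPIII genes and TPL. They are also up to 4 members of each gene list past the threshold, taking those bound in most lists, with ties going to the higher REV and then the higher TPL fold enrichment. Further, the 10 genes with the best mean rank of fold enrichment among genes in all 5 HD-ZIPIII lists were named, as were the 10 with the highest TPL fold enrichment among genes in at least 3 of them. The rule also takes the 3 strongest genes found in a single list, for each list, and every member of the PLETHORA and ANT, LITTLE ZIPPER, and KANADI and YABBY lists with a peak. A gene's fold enrichment is that of its strongest peak in a list. The values of 1 gene that the rule takes are not reported here.

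The alternatives planned before the data were examined were the stronger 50% of each list by fold enrichment, lists shortened to the length of the shortest by fold enrichment, summits within 100 bp, reciprocal overlap of 50%, null positions matched on the distance to a gene instead of to a transcription start, assignment distances of 1000 and 5000 bp, a background of genes with a peak, the peak midpoint in place of the summit, and −log10 q in place of fold enrichment. Alternatives chosen after seeing the data were shifts of only 20 to 200 kb, peaks within 2000 bp of a gene, peaks outside gene-poor surroundings, assignment to every gene within 2000 bp, 10000 random gene lists matched on gene territory, and the PHB, PHV and ICU4 lists alone.

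The statistics were tested on simulated data with known answers. Simulated peaks were placed uniformly along the chromosomes, and simulated target genes were drawn evenly over all genes. Clustering of peaks and differences in gene size were thus not imitated, so the rates below need not hold for the real lists. With lists as long as those of PHB and TPL (2790 PHB peaks), 4 of 100 simulated pairs without a planted overlap passed the threshold. A planted overlap of 2% of the peaks was called in 17 of 20 pairs, and the mean estimate was 2.03%. Gene lists with 70% of the members planted among 27444 genes were recovered in 99.5% of cases at the REV set size, 90% at the ICU4 size and 79% at the TPL size. A planted difference of 0.3 in median fold enrichment among PHB peaks was called in 40 of 40 simulations. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.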

Results

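Binding sites of 6 tagged proteins were mapped by ChIP-seq in whole Arabidopsis seedlings 10 days old. REV, PHB, PHV, ICU4 and ATHB8 make up the HD-ZIPIII family, transcription factors that promote upper (adaxial) leaf identity, shoot meristem formation and vascular patterning. ICU4 is the product of ATHB15, also called CORONA. TPL is a co-repressor that reaches DNA through the transcription factors it binds. There was 1 peak list per protein, so no value below has a replicate error, and differences between lists cannot be separated from differences between libraries. The nuclear chromosomes held 5814 REV peaks, 2790 PHB, 2872 PHV, 8964 ICU4, 4813 ATHB8 and 12785 TPL peaks. Read depth is unknown, which limits what can be said of the numbers of peaks. Median peak width was 99 bp for REV and 80 bp for ATHB8, against 183 bp for PHB, 190 bp for PHV, 223 bp for ICU4 and 564 bp for TPL. Fold enrichments are the authors' values for single peaks and are read only within a list. All coordinates are on TAIR10.

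The strongest peaks of the PHV and ICU4 lists lay next to GT18 (AT5G62220), which encodes a galactosyltransferase acting on the cell wall polymer xyloglucan. On chromosome 5 the REV peak spanned 24990481 to 24990877 and the ICU4 peak 24990451 to 24991359, and the summits of all 5 HD-ZIPIII proteins fell between 24990666 and 24990680, outside the gene. Fold enrichment there was 10.3 for REV, 9.79 for PHB, 16.7 for PHV, 22 for ICU4 and 5.04 for ATHB8. A TPL peak with a fold enrichment of 11.2 covered the same stretch, from 24988591 to 24991594. Its summit, at 24991190, lay nearer to further PHB and PHV summits at 24991097 and 24991155. HAT1 (AT4G17460), an HD-ZIPII transcription factor gene on chromosome 4, also had peaks of all 5 proteins within a TPL peak. There the TPL summit, at 9738187, lay beside theirs, between 9738147 and 9738184. Its REV peak ran from 9737989 to 9738292 and its ATHB8 peak from 9737995 to 9738287, outside the gene, inside a TPL peak from 9737676 to 9738995. A further TPL peak, with its summit inside HAT1 at 9740926, overlapped a PHV and an ICU4 peak.

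**Figure D1:**
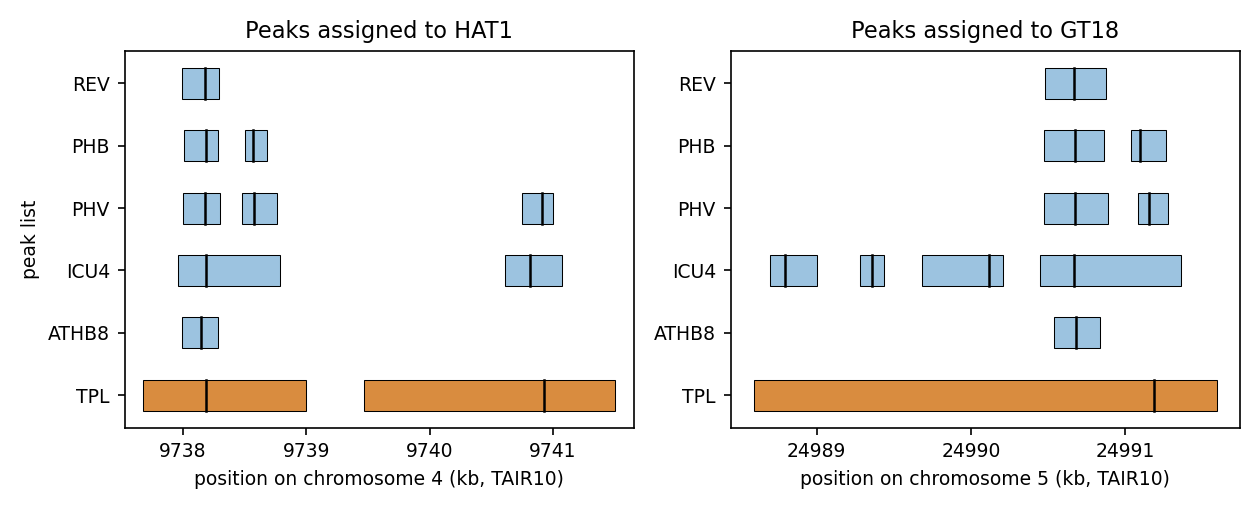
Peaks assigned to HAT1 (left) and GT18 (right) along the chromosome in kb (TAIR10), with 1 line of boxes per peak list, each box a peak and each black line its summit. The 5 HD-ZIPIII lists have a peak at a shared position within a wider TPL peak, and at HAT1 the REV peak starts at 9737989.

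Where the peaks of each protein lay relative to genes was compared first. Most REV and ATHB8 peaks lay far from protein-coding genes, and fewer ICU4, TPL and PHB peaks did so than positions placed at random. Summits inside a gene made up 67.0% of the ICU4 list (Wilson 95% interval 66.0 to 68.0), 60.5% of the PHB list, 49.9% of the PHV list and 49.8% of the TPL list. The share was 27.2% for REV (26.1 to 28.4) and 13.6% for ATHB8 (12.6 to 14.6), and positions placed at random gave 54.1%. TPL summits stood out for lying just outside genes, with 44.4% outside but within 2000 bp of one, against 27.8% of random positions. More than 2000 bp from any gene lay 59.6% of REV and 70.6% of ATHB8 summits, but 7.20% of ICU4, 5.82% of TPL and 10.8% of PHB summits. For PHV the share was 19.5% (18.1 to 21.0), no lower than the 18.0% of random positions. Gene-poor surroundings held 53.2% of REV peaks, 59.3% of ATHB8 peaks and 0.806% of TPL peaks, against 13.2% of random positions.

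**Figure D2:**
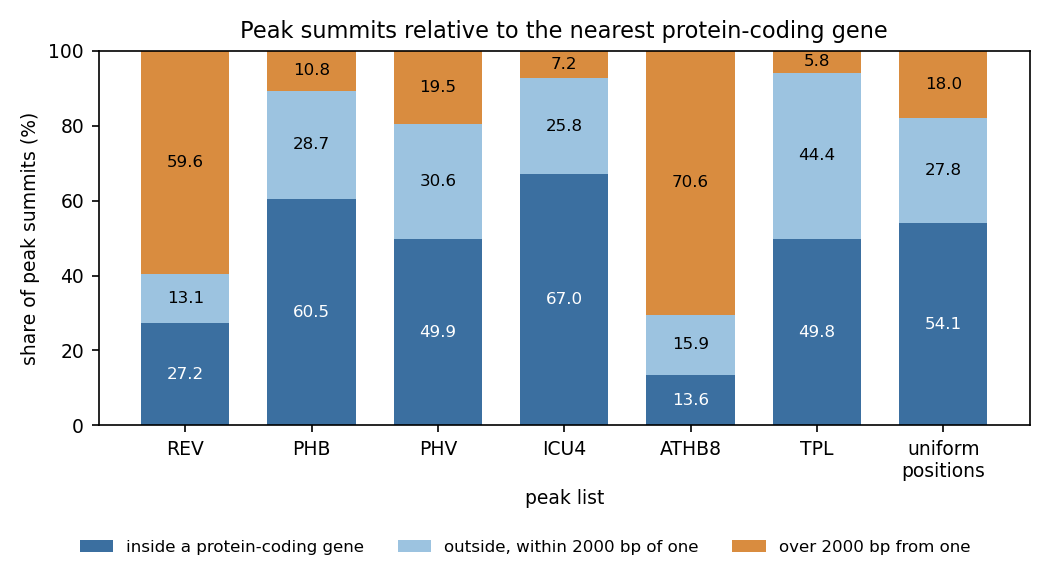
Share of peak summits (%) inside a protein-coding gene, outside but within 2000 bp of one, or farther away, for each peak list and for uniformly placed positions. Summits over 2000 bp from a gene make up 59.6% of the REV and 70.6% of the ATHB8 list.

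The series asks which targets are common to the HD-ZIPIII family. Most PHB and PHV peaks lay at an ICU4 peak, 76.2% of PHB peaks (95% interval 74.6 to 77.7) and 67.4% of PHV peaks (65.6 to 69.1), and 50.3% of PHB peaks overlapped a PHV peak. Of the longer ICU4 list, 22.2% of peaks overlapped a PHB and 20.4% a PHV peak. REV shared sites with both groups of lists, since a REV peak was overlapped by 38.3% of PHB, 42.7% of PHV and 43.6% of ATHB8 peaks. Of the ATHB8 peaks, 12.1% overlapped an ICU4 peak. Each of the 10 pairs exceeded all 1000 circular shifts of one list (one-sided permutation p = 0.001, the smallest possible). The excess over the mean shift ran from 4.14-fold for ATHB8 and ICU4 to 46.4-fold for PHB and PHV. Among peaks within 2000 bp of a gene, an alternative chosen after seeing the data, the ATHB8 and ICU4 overlap rose to 30.6% and that of REV and ICU4 from 30.5% to 64.0%. With shifts of only 20 to 200 kb, also chosen after seeing the data, the excess for ATHB8 and REV was 13.0-fold in place of 36.8-fold.

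**Figure D3:**
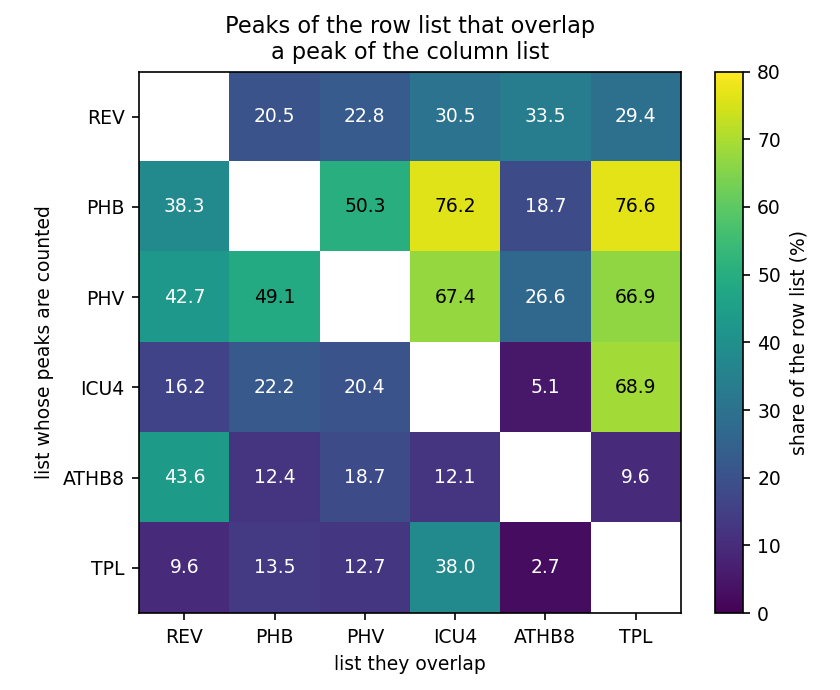
Share (%) of the peaks of the list at the left that overlap a peak of the list at the bottom by at least 1 bp, coloured from 0 to 80%. The highest HD-ZIPIII share is that of PHB peaks with an ICU4 peak, 76.2%, and the share of ATHB8 peaks with an ICU4 peak is 12.1%.

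Merged over the 5 HD-ZIPIII lists, the peaks formed 16201 regions. Of these, 255 were held by all 5 lists and 601 by 4, where the shifts gave means of 0.004 and 0.313 regions (one-sided permutation p = 0.001, the smallest possible). A further 11424 regions were held by a single list, 5884 of them ICU4 regions. The stronger part of each list left 68 regions common to all 5, lists of equal length left 99, and matching by summits within 100 bp left 163. Each of these was still above every shift. In the PHB, PHV and ICU4 lists alone, an alternative chosen after seeing the data, 1201 regions were common to all 3, against a highest shift of 11.

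With each peak given to its nearest gene within 2000 bp, 219 genes had a peak of all 5 HD-ZIPIII proteins, where independent lists would give 0.0608. Besides GT18, those with the best ranks of fold enrichment included JAZ3 (AT3G17860), a repressor of jasmonate signalling, and ARF2 (AT5G62000), an auxin response factor that represses transcription. They also included PP2CG1, a type 2C protein phosphatase gene, AGL14, which encodes a MADS-box transcription factor, ATI1, whose product interacts with the autophagy protein ATG8, SHOT1, the neighbour of the HD-ZIPII gene HAT3, and the loci AT2G22590, AT5G54530 and AT5G46910. At JAZ3 fold enrichment was 8.79 for REV, 9.55 for PHB, 9.43 for PHV, 19.2 for ICU4 and 3.73 for ATHB8, with all of these summits between 6119608 and 6119633 on chromosome 3. At PP2CG1 it was 9.40 for REV and 21.1 for ICU4, with the summits inside the gene. ARF2 had HD-ZIPIII summits inside the gene near 24910298 on chromosome 5, at a fold enrichment of 7.13 for REV and 12.0 for ICU4, and was the 1 gene of these 10 without a TPL peak. The 219 genes also took in control genes for strong transcription, among them LHCB1.1, LHCB2.3, LHCB1.5 and LHCB2.1. The comparison with independent lists thus cannot separate shared binding from signal common to strongly transcribed loci.

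In all, 1580 genes were assigned a REV peak, 1971 a PHB, 1915 a PHV, 6041 an ICU4 and 957 an ATHB8 peak. The gene sets of each pair overlapped more than independent sets of the same size. The odds ratio ran from 3.19 for ICU4 and ATHB8 (441 shared genes) to 38.6 for PHB and PHV (1103 shared genes), and the largest adjusted p among all 15 pairs with TPL included was 2.88e-19 in the two-sided Fisher exact test. The number of genes common to the 5 lists depended on how peaks were chosen and assigned: it was 68 with the stronger part of each list, 96 with lists of equal length and 396 when each peak counted for every gene within 2000 bp.

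Some genes had a peak in a single list. The strongest of these in the REV list was AT2G14775, with a fold enrichment of 15.4 in a peak from 6354918 to 6355137 on chromosome 2, followed by AT1G56420 at 6.45 and AT5G17165 at 6.04. In the ICU4 list they were AT5G47090 (6.58), AT2G34238 (5.70) and AT3G23320 (5.44), and in the ATHB8 list AT5G38040 (5.36), AT3G05410 (5.05) and AT1G45215 (4.95). The PHB list had UAP56a (3.8), an RNA helicase gene, AT3G15635 (3.68) and TL29 (3.65), whose product lies in the thylakoid lumen. The PHV list had AT1G10880 (4.17), the glutamine synthetase gene GLN1;4 (4.17) and AT2G41105 (4.07). For TPL they were AT1G56630 (13.9), AT4G16880 (12.8) and the glutamate synthase gene GLU2 (12.4). No test compared the lists at single genes, so the absence of a peak is not evidence of the absence of binding.

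The series also asks which HD-ZIPIII targets are held by TPL. A TPL peak overlapped 76.6% of PHB (95% interval 75 to 78.2), 66.9% of PHV (65.1 to 68.6) and 68.9% of ICU4 peaks (67.9 to 69.9). With lists of equal length these shares were 47.8%, 45% and 57.1%, and by summits within 100 bp 41.6%, 39.4% and 36.0%. Among REV peaks the share was 29.4%, and 11.4% with lists of equal length, 14.6% in the stronger part of the lists and 12.1% by summits. Among ATHB8 peaks it was 9.60%, and 4.41%, 4.95% and 3.01% under the same alternatives. Shifts of the TPL list gave a mean of between 9.30% and 11%. The overlap exceeded all shifts for REV, PHB, PHV and ICU4 (one-sided permutation p = 0.001, the smallest possible), by 3.07-fold, 7.23-fold, 6.32-fold and 6.25-fold, and did not for ATHB8 (1.03-fold, p = 0.448). The ATHB8 result depended on the comparison, as the excess was 0.814-fold in the stronger part of the lists, 3.41-fold against positions matched on the distance to a gene and 2.53-fold against shifts of 20 to 200 kb. Against the matched positions and these short shifts the observed share was the same, 9.60%, and the null means were 2.81% and 3.79%. Among peaks near a gene, 30.9% of ATHB8 and 70% of REV peaks overlapped a TPL peak. When the overlap had to cover 50% of both peaks, it fell to 4.3% of PHB and 0.774% of REV peaks, the TPL peaks being wider.

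TPL was more frequent at regions held by 4 HD-ZIPIII lists than at regions of 1 list. A TPL peak overlapped 36.3% of the regions held by 1 list (95% interval 35.4 to 37.1), 43.0% of those held by 2, 63.9% by 3, 83.2% by 4 (80 to 86.0) and 84.3% by all 5 (79.3 to 88.3). The intervals for 4 and 5 lists overlap, and the order of these 2 shares depended on the alternative: 63.2% and 58.3% by summits within 100 bp, but 87.3% and 94.1% in the stronger part of the lists, 64.5% and 74.7% with lists of equal length and 95.1% and 97.1% near a gene. The shares for 1 and 2 lists were 52.3% and 75.4% among peaks near a gene, 14.6% and 26.5% with lists of equal length, and 16.3% and 23.0% by summits. The shifted TPL list gave means of 9.94% to 15.5%, the wider regions of several lists being met more often by chance. Which lists hold a region also matters: among regions of 1 list the share was 60.7% for ICU4, 47.4% for PHB, 38.8% for PHV, 7.21% for REV and 1.99% for ATHB8. In the PHB, PHV and ICU4 lists alone, an alternative chosen after seeing the data, it was 55.6%, 80.3% and 90.8% for regions of 1, 2 and 3 lists. Of the 458 regions held by REV, PHB, PHV and ICU4 without ATHB8, 98.7% overlapped a TPL peak. Of the 1170 regions held by REV and ATHB8 alone, 0.342% did. Among the 255 regions of all 5 lists, the 40 without TPL were in gene-poor surroundings in 67.5% of cases, and none of the 215 with TPL were. In the other direction, 5225 of the 12785 TPL peaks (40.9%) overlapped an HD-ZIPIII region.

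**Figure D4:**
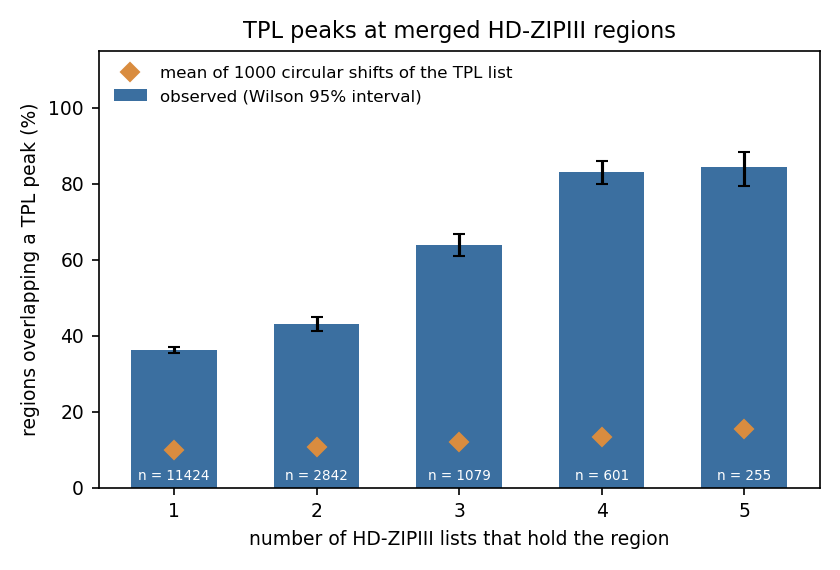
Share (%) of merged HD-ZIPIII regions overlapping a TPL peak, by the number of HD-ZIPIII lists that hold the region; bars are observed shares with Wilson 95% intervals and diamonds the mean of 1000 circular shifts of the TPL list. The share is 36.3% for regions of 1 list and 84.3% for regions of all 5.

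TPL peaks were assigned to 9234 genes, among them 202 of the 219 genes with a peak of all 5 HD-ZIPIII proteins (92.2%, 95% interval 87.9 to 95.1). Of the 20154 genes without any HD-ZIPIII peak, 21.5% had a TPL peak. The strongest TPL peak of genes bound by at least 3 HD-ZIPIII proteins was at MIPS1 (AT4G39800), which encodes an inositol phosphate synthase, with a fold enrichment of 17.8 from 18471482 to 18472912 on chromosome 4. It was followed by BOB1 (15.8), a gene needed for embryo patterning, and PIN7 (15.1), an auxin efflux carrier gene. Next came DFL2 (14.6), a GH3 family gene, AT5G12043 (14.3), TPR1 (14.2), which encodes a TPL-related co-repressor, AT2G18090 (14.2), the auxin-responsive gene IAA2 (14.0), BRG2 (13.9) and AT4G34220 (13.8). At PIN7 the TPL summit, at 8181458 on chromosome 1, lay inside the gene, as did the strongest summits of PHB (8181454), PHV (8181459), ICU4 (8181482) and REV (8181493).

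Peaks shared with TPL were the stronger ones of the PHB, PHV and ICU4 lists and the weaker ones of the REV and ATHB8 lists. Median fold enrichment with and without a TPL peak was 3.17 and 2.86 for PHB, 3.27 and 2.93 for PHV, and 3.35 and 2.80 for ICU4. It was 3.32 and 3.86 for REV, and 2.91 and 3.21 for ATHB8. Each of these 5 differences had an adjusted p of 1.25e-05 (two-sided permutation test, from the smallest p possible, 1e-05). Gene-poor peaks, few of which had a TPL peak, were the stronger ones of the REV list (median 4.0 against 3.41 for the others) and of the ATHB8 list (3.31 against 3.0). Outside gene-poor surroundings, an alternative chosen after seeing the data, the difference with TPL shrank from -0.545 to -0.273 for REV (adjusted p = 1.43e-05, permutation test) and from -0.291 to -0.115 for ATHB8 (adjusted p = 0.000922). Peaks held by 4 or 5 lists had a higher median than those of 1 list for ICU4 (by 2.49), PHB (by 0.720) and PHV (by 0.549), again with an adjusted p of 1.25e-05. By the same permutation test, the difference in the REV list was -0.136 (adjusted p = 0.0767), and in the ATHB8 list -0.0831 (adjusted p = 0.0248). In a permutation test of −log10 q, the REV difference was 0.132 (adjusted p = 0.739) and that of ATHB8 turned to 0.101 (adjusted p = 0.0222). Outside gene-poor surroundings the REV difference in fold enrichment turned to 0.178 (adjusted p = 0.00035) and that of ATHB8 was -0.0620 (adjusted p = 0.168) in the permutation test.

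The gene lists were examined for groups held by each protein. HD-ZIPII genes, which act in shade responses and leaf polarity, were among the targets of all 6 proteins: 6 of 10 had a REV peak (odds ratio 24.6, adjusted p = 8.67e-05), 7 a PHB (30.3, adjusted p = 1.52e-05), 7 a PHV (31.2, adjusted p = 1.43e-05), 8 an ICU4 (14.2, adjusted p = 0.00134), 3 an ATHB8 (11.9, adjusted p = 0.0147) and 9 a TPL peak (17.8, adjusted p = 0.00303), by the two-sided Fisher exact test. HAT1, HAT2 and HAT22 had a peak in all 6 lists and ATHB2 in all but ATHB8. Fold enrichment in the ICU4 list was 12.2 at HAT1, 10.9 at HAT2 and 8.23 at both HAT22 and ATHB2. The control list of light-harvesting and RuBisCO genes was enriched in every list as well. Of its 22 members, 14 had a REV, 15 a PHB, 14 a PHV, 18 an ICU4, 13 an ATHB8 and 20 a TPL peak, with odds ratios in the Fisher exact test from 16.0 (ICU4, adjusted p = 1.05e-07) to 40.5 (ATHB8, adjusted p = 4.87e-12). LHCB2.3 and LHCB1.5, genes of the photosystem II antenna, had an ICU4 fold enrichment of 7.72 each, and LHCB1.1 and LHCB2.1 had 5.70 and 7.05.

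Genes of auxin transport were targets of all 6 proteins too, beside the enriched control list. The counts were 4 of 12 members for REV (adjusted p = 0.0143, Fisher exact test), 6 for PHB (0.000987), 5 for PHV (0.00516), 7 for ICU4 (0.0216), 3 for ATHB8 (0.0226) and 9 for TPL (0.0147), and odds ratios from 4.96 to 13.0. PIN7 and PIN3 had a peak in all 6 lists, and the influx carrier gene LAX1 in all but ATHB8. At LAX1 the ICU4 fold enrichment was 6.55 and the TPL fold enrichment 9.74. Of the 29 Aux/IAA genes, which encode auxin-response repressors that recruit TPL, 7 had a PHB (odds ratio 4.12, adjusted p = 0.0143), 6 a PHV (3.49, adjusted p = 0.0388), 13 an ICU4 (2.88, adjusted p = 0.0197) and 20 a TPL peak (4.39, adjusted p = 0.00112), by the exact test. REV peaks were at 2 of them and ATHB8 peaks at 1, which did not pass the exact test (adjusted p = 0.843 and 1). IAA2 had a peak in all 6 lists, IAA16 in 5, and IAA19 and IAA1 in the PHB, PHV, ICU4 and TPL lists. Among 15 auxin response factor genes, 11 had a TPL peak (odds ratio 5.43, adjusted p = 0.00911, exact test), among them ARF19 (fold enrichment 12.3), ARF10 (9.19) and ARF8 (5.34). The HD-ZIPIII counts at these genes, 2 REV, 2 PHB, 3 PHV, 7 ICU4 and 1 ATHB8, did not pass.

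Genes of TPL and its relatives were themselves targets, again with the control list enriched in the same lists. All 5 had a TPL peak (adjusted p = 0.0147), 4 had a PHB (odds ratio 51.8, adjusted p = 0.00113), 4 a PHV (53.4, adjusted p = 0.00112), 4 an ICU4 (14.2, adjusted p = 0.0283) and 3 a REV peak (24.6, adjusted p = 0.00845), by the Fisher exact test, while ATHB8 had 1. TPR2 had a peak in all 6 lists, with a TPL fold enrichment of 11.9, TPL and TPR3 in all but ATHB8, and TPR1 in the PHB, PHV, ICU4 and TPL lists. JAZ genes, whose products repress jasmonate responses, were targets of all 6 proteins: 6 of 12 for REV (odds ratio 16.4, adjusted p = 0.000311, exact test), 5 each for PHB (9.25, 0.00562) and PHV (9.54, 0.00516), 8 for ICU4 (7.09, 0.00627), 4 for ATHB8 (13.9, 0.00392) and 10 for TPL (9.87, 0.00392). JAZ3, JAZ1 and JAZ6 had a peak in all 6 lists and JAZ5 in all but ATHB8.

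Hormone and light signalling gave further groups, beside 14 of 22 control genes in the REV list and 18 of 22 in the ICU4 list. Of 8 abscisic acid receptor genes, 3 had a REV (odds ratio 9.84, adjusted p = 0.0257, exact test), 4 a PHB (12.9, adjusted p = 0.00745), 6 an ICU4 (10.6, adjusted p = 0.00911) and 7 a TPL peak (13.8, adjusted p = 0.0112), while 2 had a PHV and 1 an ATHB8 peak. The REV count was 0 with the stronger part of the list and with lists of equal length, and no call for these receptors passed under every alternative. PYL4 had a peak in all 6 lists, PYL5 in all but ATHB8, PYL6 in the REV, PHB, ICU4 and TPL lists and PYL1 in the PHB, ICU4 and TPL lists. Of 8 shade and PIF genes, 3 had a PHB (odds ratio 7.76, adjusted p = 0.0431, exact test), 3 a PHV (8.01, adjusted p = 0.0408), 6 an ICU4 (10.6, adjusted p = 0.00911) and 7 a TPL peak (13.8, adjusted p = 0.0112), against 2 for REV and 0 for ATHB8. PIF5, a transcription factor gene of the shade response, had fold enrichments of 7.57 for PHV and 10.2 for TPL, and PAR1, PAR2 and PIF4 had TPL values of 8.82, 10.3 and 7.64. Clock genes passed the exact test for ICU4 (7 of 12, odds ratio 4.96, adjusted p = 0.0216) and TPL (10 of 12, odds ratio 9.87, adjusted p = 0.00392), with 1 REV, 2 PHB, 1 PHV and 1 ATHB8 peak. PRR9 had a peak in all 6 lists, and CCA1, LHY and GI had TPL fold enrichments of 10.6, 9.29 and 8.08. Stomatal lineage genes passed the exact test for TPL, with 9 of 11 (odds ratio 8.88, adjusted p = 0.00745), among them EPF2 (8.72), ERL2 (8.69), BASL (8.22) and TMM (6.06). Counts for the others were 3 REV, 3 PHB, 1 PHV, 6 ICU4 and 1 ATHB8, none of which passed.

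**Figure D5:**
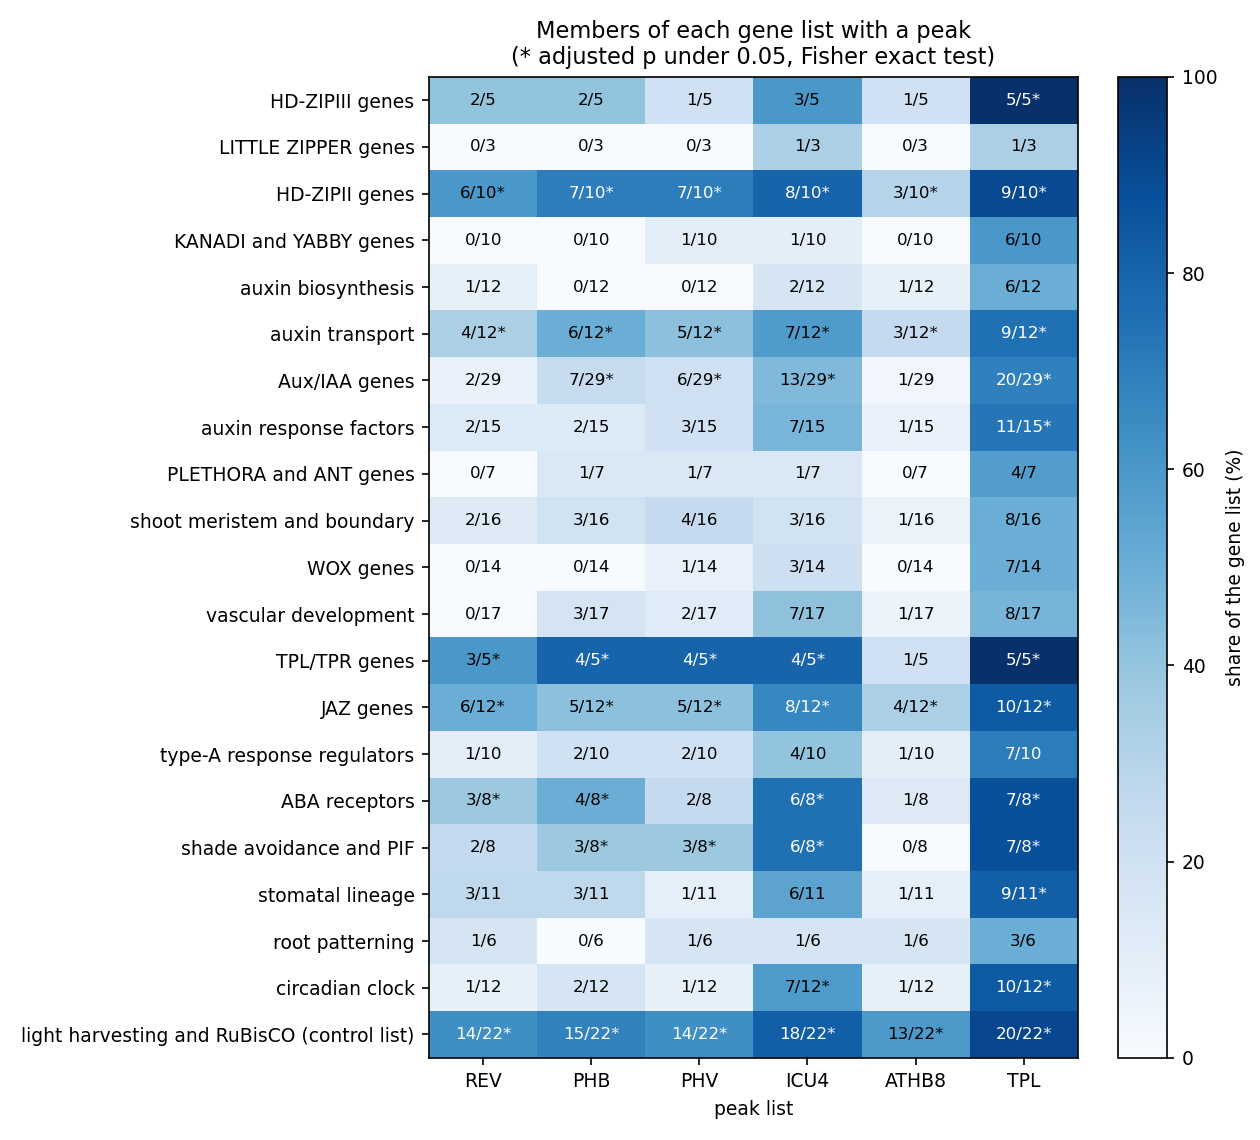
Number of members of each gene list with a peak in each peak list, coloured by share (%) of the gene list; asterisks mark an adjusted p under 0.05 in the Fisher exact test. The control list of light-harvesting and RuBisCO genes is enriched in all 6 lists, with 13 of 22 members for ATHB8 and 20 of 22 for TPL.

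All 5 HD-ZIPIII genes had a TPL peak (adjusted p = 0.0147, two-sided Fisher exact test), and each protein except PHV had a peak at its own gene. Peaks at the own gene may come from extra copies brought by the tagged construct, an explanation left open below. The strongest ICU4 peak at ATHB15 had a fold enrichment of 7.98 and lay outside the gene, from 19415292 to 19415979 on chromosome 1. PHB and TPL also had a peak there. The PHB gene had peaks of REV (3.32), PHB (2.91), PHV (3.72), ICU4 (4.69) and TPL (9.23). The REV gene had a REV peak at 2.70, the PHV gene an ICU4 peak at 3.87 and the ATHB8 gene an ATHB8 peak at 2.54. Of the 5 genes, 2 had a REV, 2 a PHB, 1 a PHV, 3 an ICU4 and 1 an ATHB8 peak, and these counts did not pass. In the HD-ZIPIII lists, all 10 peaks with a summit inside one of these genes belonged to the list of the protein that gene encodes, 2 in REV, 3 in PHB and 5 in ATHB15. Of the LITTLE ZIPPER genes, which encode small inhibitors of HD-ZIPIII proteins, ZPR3 had an ICU4 peak (3.90) and a TPL peak (1.88), and ZPR1 and ZPR2 had no peak.

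The KANADI and YABBY genes act in lower (abaxial) leaf identity, opposite to HD-ZIPIII genes, and 6 of 10 had a TPL peak (odds ratio 2.96, adjusted p = 0.206), which did not pass the exact test. PHV and ICU4 had a peak at 1 of them each, and REV, PHB and ATHB8 at 0. FIL (fold enrichment 6.27), YAB3 (4.89), KAN1 (3.45), YAB5 (3.03) and CRC (2.97) had a TPL peak alone, and KAN3 had a PHV (3.99), an ICU4 (4.05) and a TPL peak (6.29). PLETHORA and ANT genes, regulators of stem cell and organ growth, had a TPL peak in 4 of 7 cases (adjusted p = 0.407, exact test), at PLT5, PLT7, ANT and PLT3. PLT5 also had a PHB (4.23), a PHV (4.26) and an ICU4 peak (3.53), near 23257136 on chromosome 5. No other member of this list had an HD-ZIPIII peak.

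The remaining lists did not pass in any peak list. Auxin biosynthesis genes had 1 REV, 0 PHB, 0 PHV, 2 ICU4, 1 ATHB8 and 6 TPL peaks at 12 genes. Shoot meristem and boundary genes had 2, 3, 4, 3, 1 and 8 in the same order at 16 genes, and WOX genes 0, 0, 1, 3, 0 and 7 at 14. Vascular genes had 0, 3, 2, 7, 1 and 8 at 17, type-A response regulators 1, 2, 2, 4, 1 and 7 at 10, and root patterning genes 1, 0, 1, 1, 1 and 3 at 6. Of these, WUS, which maintains the shoot stem cells, had a PHV peak at a fold enrichment of 2.27, and SHR, a root patterning gene, had peaks of REV (2.93), PHV (3.38), ICU4 (5.82) and TPL (3.44), both genes having been chosen after their values were seen.

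Across the 126 tests, 46 combinations of a gene list and a peak list were enriched and none depleted, 6 of them for REV, 8 for PHB, 7 for PHV, 9 for ICU4, 4 for ATHB8 and 12 for TPL. Against a background of genes with a peak in at least 1 list, 35 of the 46 no longer passed, including each of those for ICU4 and TPL. The 9234 TPL targets make up most of that background, so gene lists of this size had little room to pass for TPL. The loss of the TPL calls there, which also keeps them out of the calls below, is therefore no measure of their strength. The combinations that passed under every alternative numbered 9. They were HD-ZIPII genes for REV and PHV, JAZ genes for REV, TPL and its relatives for PHB and PHV, auxin transport for PHB, and the control list for REV, PHB and ATHB8.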

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

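All tests in this part were chosen after the result they bear on had been seen. ICU4 was the protein with peaks on the chloroplast chromosome, 75 of them, with fold enrichments from 1.25 to 1.66, and these peaks lie outside the nuclear comparisons. No list of a control immunoprecipitation was used here, so the comparison is with the other 5 lists, which held no chloroplast peak.

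REV and ATHB8 peaks lay in gene-poor surroundings in 53.2% and 59.3% of cases, and these peaks were narrow. Chance positions are argued against, since 42.9% of the gene-poor REV peaks (1327 of 3093) overlapped a gene-poor ATHB8 peak and shifts of 20 to 200 kb reached at most 6.08%. Whether such sites are collected in every library of this strain could not be decided by the overlap with TPL peaks. The TPL list held 103 gene-poor peaks in all, so few of the 1262 gene-poor regions held by both lists could overlap one. The share was 0.238%. Of these regions, 247 (19.6%) overlapped a PHV, 92 (7.29%) a PHB and 76 (6.02%) an ICU4 peak. Those 3 lists held 340, 153 and 387 gene-poor peaks in all, which limited these shares as well. The PHV and PHB lists, whose peaks were wider, thus also held part of these sites. The TPL share shows only that the regions were rarely called in the TPL list. A property of these libraries, such as fragment length, may be the source and cannot be told apart from the proteins, each of which has 1 library: the smallest peak width in the other 4 lists was 2.14 times the larger of the smallest widths of REV and ATHB8. That REV and ATHB8 themselves bind such regions stays open as a biological explanation that was not tested.

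The control genes for strong transcription were enriched in all 6 lists, as were HD-ZIPII, JAZ and auxin transport genes, and Aux/IAA genes in 4. Collection of transcribed gene bodies without binding is a candidate explanation for the HD-ZIPIII peaks at the control genes, since 95.2% of these targets (20 of 21) had most of their strongest summits inside the gene, against 66.9% of all HD-ZIPIII target genes, and stays open for TPL, with 55% inside (11 of 20, 34.2 to 74.2) against 51.3% of all TPL targets. Summit positions argue against it for HD-ZIPIII peaks at HD-ZIPII genes, at 12.5% (1 of 8, 95% interval up to 47.1%). They do so as well for HD-ZIPIII peaks at Aux/IAA genes, at 15.4% (2 of 13, up to 42.2%). The strongest summits at both lay mostly outside the gene. For TPL peaks it stays open, at 22.2% for HD-ZIPII genes (2 of 9, up to 54.7%) and 30% for Aux/IAA genes (6 of 20, up to 51.9%). For HD-ZIPIII peaks at JAZ genes, at 25% of 8, and auxin transport genes, at 42.9% of 7, it cannot be told apart from binding because the members are few. By single list, the strongest summit at JAZ genes lay inside for 66.7% of REV (4 of 6) and 75% of ATHB8 targets (3 of 4). The share was 20% (1 of 5) for PHB and for PHV and 37.5% (3 of 8) for ICU4. Abscisic acid receptors and shade and PIF genes, at 66.7% each (4 of 6), stood near the 66.9% of all HD-ZIPIII target genes. Collection of gene bodies stays open there too. Signal at open promoters that does not need the tagged protein was not tested, since no untagged plants were among the samples, and binding by each protein stays open.

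All 10 HD-ZIPIII peaks with a summit inside one of the 5 HD-ZIPIII genes were in the list of the protein that the gene encodes, at REV, PHB and ATHB15. Extra copies of the gene brought by the tagged construct may give such peaks, as reads of the construct would map to the gene. The input of the same line would carry the same copies, so copy number alone would raise signal and background together. Whether the input fully corrected for such copies was not tested. In the ICU4 list a pileup of 32 went with a fold enrichment of 2.69 inside ATHB15 and 4.18 at the PHB gene. In the PHB list a pileup of 41.96 inside PHB went with 2.23, and 40.16 at HAT2 with 4.57. The local background was thus higher at these own genes than at the loci compared, which goes with extra copies. In the REV list a pileup of 22.57 went with 2.70 inside REV and 2.62 at HAT22, so there it was not higher. Peaks inside the own gene were found in 3 of the 5 lists, those of PHV and ATHB8 having none. Extra copies thus stay open and cannot be told apart from binding of the proteins to their own genes, which was not tested. The same holds for the TPL peak at the TPL gene, whose summit lay outside that gene.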

How the results depend on the processing

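Tests against shifts of 20 to 200 kb, on peaks near a gene, outside gene-poor surroundings, with every gene within 2000 bp, on territory-matched random lists and on 3 lists alone were chosen after seeing the data. The 10 pairwise overlaps of HD-ZIPIII lists kept their direction and their side of the threshold in 70 of 70 alternatives run, the regions of all 5 lists in 5 of 5, and the TPL overlaps in 54 of 60, the exceptions being ATHB8. The excess of ATHB8 peaks at TPL peaks, 1.03-fold, was 0.814-fold in the stronger peaks, 0.736-fold with reciprocal overlap and 1.39-fold by summits (one-sided permutation p = 0.0150). It was 3.41-fold against gene-matched positions, 2.53-fold against short shifts and 3.48-fold near genes. For gene-matched positions and short shifts the observed share stayed at 9.60%. The mean of the null positions fell from 9.30% to 2.81% and 3.79%, so the choice of null made this change. For the other alternatives the cause was not tested. Numbers of target genes moved by construction, since fewer peaks or more genes per peak entered. With the stronger peaks they were 586 for REV, 1099 for PHB, 1029 for PHV, 3415 for ICU4, 402 for ATHB8, 5131 for TPL and 68 for all 5 HD-ZIPIII lists. With equal lengths they were 546 for REV, 2196 for ICU4, 486 for ATHB8, 2351 for TPL and 96 for all 5. With every gene within 2000 bp they were 2677 for REV, 3476 for PHB, 3240 for PHV, 10015 for ICU4, 1505 for ATHB8, 14333 for TPL and 396 for all 5. PHB, PHV and ICU4 alone had 1052 common genes. Enriched gene lists numbered 3 for REV and 4 for PHV with the stronger peaks, 3 for REV and 2 for ATHB8 with equal lengths, 2 for ATHB8 and 6 for TPL with every gene within 2000 bp, and 2 for ATHB8 and 7 for TPL against territory-matched lists. Against genes with a peak they were 3 for REV, 4 for PHB, 3 for PHV, 0 for ICU4, 1 for ATHB8 and 0 for TPL, whose targets make up most of that background. Of 46 calls, 9 passed under every alternative and 20 under every one but this background. Abscisic acid receptors had 0 REV targets with the stronger peaks and with equal lengths. By midpoint, 54.5% of TPL peaks lay inside a gene. With −log10 q the difference between peaks in 4 or 5 lists and in 1 reversed to 0.132 for REV and 0.101 for ATHB8, and outside gene-poor surroundings it reversed to 0.178 for REV and was -0.0620 for ATHB8 (adjusted p = 0.168, permutation test), and the cause was not tested. The number of lists with a peak at a named gene was the same in 350 of 465 cases, over 93 genes. A longer promoter, the authors' annotation and the 3 motif alternatives were not run, for want of strand, sequence or annotation in the tables used. Depth is unknown, so lists of different lengths do not show that one protein has more sites.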

Other observations

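All tests in this part were chosen after seeing the data. Genes of 6 kinds that encode no protein were compared with the peak lists. The control genes for strong transcription were enriched in all 6 lists, and no untagged plants were among the samples. A peak near these genes therefore does not by itself show binding by the tagged protein. Of 625 nuclear tRNA genes, 327 lay within 100 bp of a TPL peak, 4.70 times the mean of the shifted lists, and 179 within 100 bp of an ICU4 peak, 6.95 times that mean (adjusted p = 0.00514 for both, two-sided permutation test, from the smallest p possible). PHV had 26 (3.49 times, adjusted p = 0.00959), PHB 18 (2.51 times, adjusted p = 0.0225), REV 19 (1.66 times, adjusted p = 0.183) and ATHB8 2 (0.240 times, adjusted p = 0.0981) by the same permutation test. Against shifts of 20 to 200 kb, which keep peaks in the same part of the chromosome, REV had 2.52 times as many (adjusted p = 0.00423), PHB 2.13 times (0.0144) and ATHB8 0.524 times (0.643, permutation test). Of 82 snRNA genes, which encode RNAs of the spliceosome, 33 had a TPL peak (3.25 times) and 20 an ICU4 peak (5.11 times), with the same adjusted p of 0.00514 in the permutation test. REV had 6 (3.37 times) and PHV 5 (4.47 times), both with an adjusted p of 0.0503, which fell to 0.00423 and 0.0344 in the permutation test with the short shifts (6.35 and 4.02 times). PHB had 3 (2.67 times, adjusted p = 0.30, permutation test) and ATHB8 none. For snoRNA genes ICU4 stood at 0.244 times the shifted lists (adjusted p = 0.0503) and TPL at 0.495 times (0.0856), and with the short shifts at 0.197 (0.0229) and 0.388 times (0.00799), by permutation tests. For miRNA genes ICU4 stood at 0.574 times (adjusted p = 0.183), TPL at 0.875 times (0.578) and REV at 0.140 times (0.0465) by the permutation test.

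Of 3917 pseudogenes, a class that in the gene table includes transposon-type entries, 957 lay within 100 bp of an ATHB8 peak (4.28 times the shifted lists) and 805 within 100 bp of a REV peak (2.87 times), but 119 of an ICU4 peak (0.194 times) and 64 of a TPL peak (0.0610 times). Against the short shifts the ratio was 1.57 for ATHB8, 1.3 for REV, 0.483 for ICU4 and 0.203 for TPL. Each of these had an adjusted p of 0.00514 or, with the short shifts, 0.00423, by two-sided permutation tests adjusted over 36 comparisons. For PHB the ratio was 0.471 (adjusted p = 0.00514) and with the short shifts 0.990 (adjusted p = 1), and for PHV it was 0.926 (adjusted p = 0.620) and 1.33 (adjusted p = 0.00423), by the same permutation tests. Long non-coding RNA genes had 2.38 times the shifted lists for PHB, 2.26 for PHV, 1.97 for ICU4, 1.86 for TPL and 0.442 for ATHB8 (adjusted p = 0.00514 for each, permutation test), and 1.05 for REV (adjusted p = 0.668). With the short shifts the REV ratio was 1.46 (adjusted p = 0.00423) and that of ATHB8 0.667 (adjusted p = 0.0206), by permutation test.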
